A study of Rangifer tarandus with 8 samples.

How the data were processed

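The series profiled open chromatin in single cells of reindeer (Rangifer tarandus) skin by single-cell ATAC-seq. In this assay a transposase cuts accessible DNA, and each fragment is read with a barcode of its cell. Per the labels, 8 libraries were made from velvet (the skin that covers the growing antler), from back skin, and from velvet grafted onto the back. Dead cells were removed by scatter gating and a viability dye, and the epidermis was taken off with dispase before the dermis was digested. The extraction text in the labels describes a 3' cDNA protocol, whereas the series design text and the library label name the single-cell ATAC kit; the libraries are treated here as ATAC libraries, as their titles say.

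Per the series text, the reads were aligned to a cattle (Bos taurus) reference, and the peak matrices of matched back and antler libraries were handled with Signac 1.2.1. Per the submitters' processing notes, the tools were Cell Ranger ATAC and Cell Ranger and the genome build was ARS-UCD1.2. The versions of both Cell Ranger tools and the peak caller's settings are not given in the sources used here. Reindeer fragments mapped to a cattle genome can only be placed where the species align, so every coordinate below is a cattle coordinate.

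The 1 deposited file used here is the gene annotation of that reference. Per the file header it belongs to ARS-UCD1.2, and its records carry Ensembl identifiers. Its values are the first and last base of each feature, counted from 1, and belong to no sample. Peak matrices, fragments and accessibility values per cell were not analysed here, so no depth per cell is known, no gene or region was compared between libraries, and no p-value describes the tissues. The number of cells per library is the submitters' own figure in the sample labels. How doublets were treated is not given in the sources used here, so these numbers can include barcodes that hold more than 1 cell.

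Samples were grouped by their titles into 7 groups, of which 6 hold 1 library and the 6-week graft group holds 2, from 2 animals. No test between groups was made, since only the 6-week grafts give any spread between libraries, and cell numbers are set side by side as ratios with no error.

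From the annotation, each protein coding gene was given a gene-activity window: the gene body plus 2 kb upstream of its start, the interval over which Signac by default adds up fragments to score a gene. For 15 lists holding 247 genes, written by hand before the data were examined, 3 quantities were computed: the median window length, the share of genes whose window overlaps the window of another protein coding gene by 1 base or more, and the mean number of distinct transcript start positions. The lists came from general knowledge of skin, wound and antler biology, and those of velvet-type and inflammatory fibroblast genes drew in part on what is known of the study's published findings. They are therefore not independent of the study, and their names describe no accessibility or expression measured here. Each value was placed among 10000 random lists of the same size drawn from the 17450 symbols held by 1 protein coding gene; for the shared share, the random lists were matched on window length in 10 bins. The resulting percentile describes the annotation and is not a p-value. Random lists that tied with the observed value were split evenly between those below and those above it. Genes were taken by the first name field of their record. For the velvet-type and inflammatory lists, the medians of log2 window length were compared by a two-sided permutation test with 100000 resamples, chosen after the medians of all lists had been seen. To allow for that choice, all list genes were reshuffled over the 15 lists 10000 times, and the largest difference between any 2 list medians was recorded each time. Intervals on shares are exact Clopper-Pearson 95% intervals, those on medians are order-statistic intervals, and those on means are bootstrap intervals; all treat the genes of a list as a draw from a wider set.

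The genes named in the text were chosen by a rule written before the data were examined: 25 genes of interest with their positions and, in each list, symbols not found, the longest and the shortest window, the gene with the largest part of its window shared, and the gene with the most start sites (where ties occur, as given). Genes outside this rule are named as such. The shortest windows of the AP-1 list and of the Schwann and melanocyte list are not reported here. Alternatives planned beforehand were an upstream extension of 0 or 5 kb, leaving out genes over 500 kb, counting neighbours of any biotype, a minimum overlap of 10% of the window, merging starts within 500 bases, matching symbols without regard to case, and protein coding genes only. Head-to-head neighbours and annotated 5' UTRs were added after seeing the data.

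The overlap code and the percentile of shared windows were tested on 3000 simulated genes with known overlaps, all on the plus strand. The start-site count was checked only on a few made-up transcripts. The random lists for median windows and mean start sites were not tested. All 3000 overlap calls came out as constructed. Of 100 random lists of 20 simulated genes, 7 fell outside the central 95% of the percentile scale, and of 100 lists built with 19 of 20 members overlapping, 100 lay above the 97.5th percentile. The work used Python 3.11.15 with numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9, and R 4.3.3 with rtracklayer 1.62.0.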

Results

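Single-cell ATAC-seq libraries were made from adult reindeer skin to set velvet, described in the series text as regenerating after wounding, against back skin, described as non-regenerating. Velvet and back skin were each sampled unwounded (day 0) and 7 days after full-thickness excisions of 12 mm. A further 4 libraries came from velvet transplanted to the back, taken 6 weeks (2 animals), 3 months and 6 months after grafting. The accessibility values behind these libraries were not analysed here. What could be measured is the number of cells recovered in each library and the gene annotation through which the study's chromatin fragments would be assigned to genes. No difference in chromatin between velvet and back skin, between days, or between graft and donor site is reported.

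The labels gave 66427 recovered cells over 8 libraries. At day 0, velvet yielded 17843 cells and back skin 20002, a ratio of 0.892. At day 7 the order was the other way, with 7176 cells from velvet and 5773 from back skin, a ratio of 1.24. The day 7 libraries held 40.2% as many cells as the day 0 library in velvet and 28.9% in back skin. Each of these groups was a single library, so none of the ratios has a replicate check. The day 0 libraries together held 57.0% of all cells.

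The libraries of grafted velvet held fewer cells at 6 weeks than the single library at each later time. How many cells went into any library was not analysed here, so cell numbers describe the libraries and not the tissues. Animal 1 gave 1006 cells and animal 2 gave 1789 at 6 weeks, which differ by a ratio of 1.78 within the same group. The 3-month graft, labelled animal 2, gave 7722 cells and the 6-month graft gave 5116. The labels do not say whether animal 2 is the same animal at 6 weeks and 3 months, so these libraries were not paired. Across all libraries the largest number was 19.9 times the smallest. Fragments per cell were not analysed here, so these numbers give no depth.

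**Figure D1:**
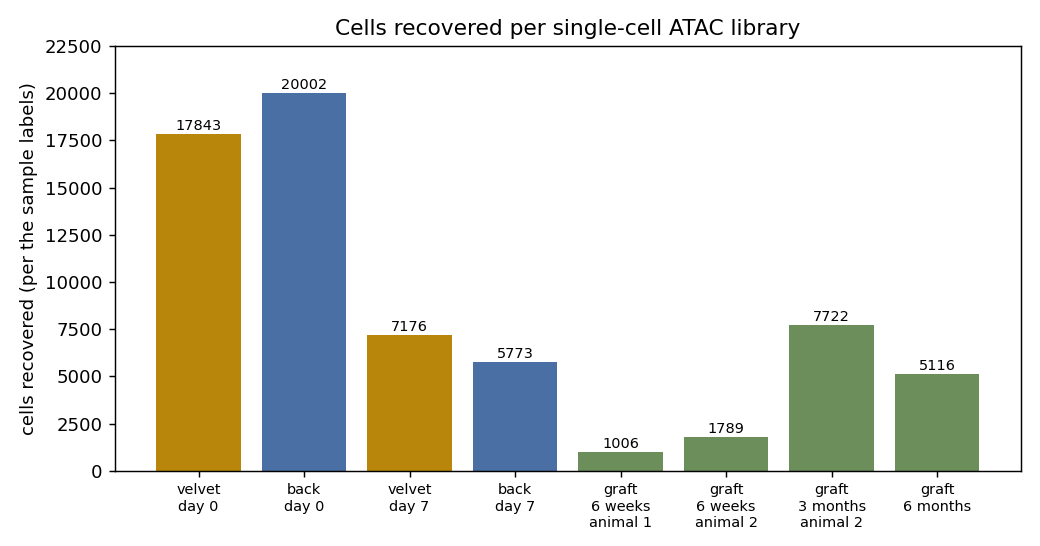
Cells recovered per library (vertical axis, number of cells given in the sample labels) for each of the 8 libraries, 1 bar per library with no error bars. The unwounded libraries stand highest at 17843 and 20002 cells and the 6-week grafts lowest at 1006 and 1789.

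The annotation placed 27607 genes and 43984 transcripts on the cattle assembly ARS-UCD1.2. Protein coding genes numbered 21861, long noncoding RNA genes 1480, small nuclear RNA genes 1201 and microRNA genes 951. The 29 autosomes carried 26101 genes, the X chromosome 1132, the mitochondrial genome 37, and 147 unplaced scaffolds the other 337. A symbol was given to 17591 protein coding genes (80.5%), and the other 4270 carried only an Ensembl identifier. Long noncoding RNA genes were almost all unnamed, with 6 symbols among 1480 genes. Among protein coding genes with a unique symbol, the median gene-activity window was 21.4 kb, 29.8% of windows overlapped that of another protein coding gene, and genes had 1.5 start sites on average.

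Of the 247 genes on the lists, 244 were found by symbol. The symbols CXCL1, TIMP1 and LOR had no match, and these genes were not analysed here. A pair of related names was looked up afterwards and lies outside the naming rule. A gene named LORICRIN, the current human symbol for LOR, lay on chromosome 3 from 17212343 to 17213356. A gene named GRO1, a former human symbol of CXCL1, lay on chromosome 6 from 89072611 to 89075133, 9.25 kb from the neutrophil chemokine gene CXCL3; whether it is the cattle counterpart of CXCL1 was not tested. IVL, which encodes the keratinocyte envelope protein involucrin, was annotated as a pseudogene, which left 243 coding genes for the measures below.

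Genes of the velvet-type and papillary fibroblast list were long, and genes of the inflammatory fibroblast mediator list were short. The 18 velvet-type genes had a median window of 74.6 kb (95% interval 24.6 to 111 kb), at the 99.9th percentile of random lists. The 25 inflammatory mediators had a median of 9.62 kb (5.70 to 12.7 kb), at the 0.76th percentile. The medians differed 7.75-fold, and a two-sided permutation test over the genes of both lists (100000 resamples, log2 length) gave p = 0.00038. This pair was picked after the medians of all 15 lists had been seen. With that choice allowed for, 1018 of 10000 reshuffles of the list genes gave a difference as large between some pair of lists (permutation p = 0.102). Chance was therefore not excluded. This p sets the pair against the largest difference among all lists, the smallest of which holds 7 genes. It does not show that the difference is absent. Genes are not independent replicates, and both p-values describe the lists, not the tissues. Of the velvet-type genes, 16 of 18 lay above the inflammatory median, and 23 of 25 inflammatory mediators lay below the velvet-type median.

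Among the velvet-type genes, RUNX1, a transcription factor gene, had the longest window at 272 kb (ENSBTAG00000004742, chromosome 1, 146975141 to 147244722). MDK, which encodes the growth factor midkine, had the shortest at 5.78 kb (ENSBTAG00000007740, chromosome 15, 76374118 to 76377898). Midkine's window was also the most shared of the list, with 44.7% of it lying within the windows of DGKZ and CHRM4. CRABP1, a retinoic acid binding protein gene, had a window of 9.20 kb (ENSBTAG00000012909, chromosome 21, 30733397 to 30740592), with 1 start site and no overlap. The tenascin genes were longer: TNC spanned 104208978 to 104311676 on chromosome 8 with 3 start sites, and TNN spanned 56325447 to 56386531 on chromosome 16 with no annotated 5' UTR. DPP4, a cell surface peptidase gene, also had 3 start sites. TWIST2, a mesenchymal transcription factor gene, lay on chromosome 3 from 118051375 to 118103633.

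The inflammatory mediators ranged from CCL8, a monocyte chemokine gene with a window of 4.03 kb, to NFKB1, a subunit gene of the NF-κB transcription factor, with 125 kb. CCL2, another monocyte chemokine gene, had a window of 4.59 kb (ENSBTAG00000037811, chromosome 19, 15902777 to 15905368), and IL6 had one of 6.38 kb (ENSBTAG00000014921, chromosome 4, 31454749 to 31459131). PTGS2, the inducible prostaglandin synthase gene, lay on chromosome 16 from 67728006 to 67735629. The longer members included CXCL12 at 31.3 kb (ENSBTAG00000005077, chromosome 28, 45022356 to 45051627), CSF1, the macrophage growth factor gene, at 22.5 kb (ENSBTAG00000000283, chromosome 3, 33488957 to 33509479), and complement C3 at 38.9 kb (ENSBTAG00000017280, chromosome 7, 17773675 to 17810616). Only 2 of the 25 windows (8%, 95% interval 0.984 to 26.0%) overlapped that of another coding gene, against a mean of 35.8% in length-matched random lists, at the 0.105th percentile. As a share of the window, the larger of these overlaps was in CSF2, at 19.4%, with the window of an unnamed gene. A single start site was annotated for 22 of the 25 genes, and LIF, NFKB1 and RELA had 2 each.

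Myofibroblast and scar matrix genes had a median window of 38.4 kb (18.4 to 95.3 kb), at the 93.8th percentile and so within the central 95% of random lists. They ran from LRRC15 at 3.76 kb to the fibrillar collagen gene COL11A1 at 228 kb. ACTA2, which encodes smooth muscle actin, had 4 start sites (ENSBTAG00000014614, chromosome 26, 10626803 to 10679430) and shared 8.88% of its window with the window of FAS. The window of TGFB1 lay wholly within those of B9D2, CCDC97 and an unnamed gene. COL1A1 (ENSBTAG00000013103, chromosome 19, 36457658 to 36474513) and COL3A1 (ENSBTAG00000021466, chromosome 2, 7375289 to 7414912) had 1 start site each and shared no sequence with a neighbour's window. EN1, a homeobox gene that marks a scar-forming fibroblast lineage in mouse back skin, lay on chromosome 2 from 70609618 to 70614377 with no annotated 5' UTR.

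Transcription factor lists had short windows. AP-1 and early response factors had a median of 6.72 kb (0.41st percentile), and the longest was that of BATF at 24.1 kb. FOS (ENSBTAG00000004322, chromosome 10, 86488645 to 86492108) and JUN (ENSBTAG00000004037, chromosome 3, 87265962 to 87268007) stood clear of other windows, whereas the window of FOSL1 lay wholly inside that of an unnamed coding gene. Cranial and limb patterning factors had a median of 7.16 kb (0.26th percentile), from TWIST1 at 4.0 kb to TBX15 at 126 kb. The most shared window of this list was that of DLX6, at 30.2%, and TFAP2A had the most start sites, 4. DLX5 lay on chromosome 4 from 14404123 to 14408479 and ALX4 on chromosome 15 from 74373004 to 74417594.

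HOX genes, which mark position along the body axis, had the shortest windows of the 15 lists, with a median of 4.69 kb (4.24 to 5.12 kb), below all 10000 random lists. The 39 genes sat in 4 clusters: HOXA on chromosome 4 (106 kb), HOXB on chromosome 19 (167 kb), HOXC on chromosome 5 (116 kb) and HOXD on chromosome 2 (96.4 kb). Windows overlapped for 14 of 39 genes (35.9%, 95% interval 21.2 to 52.8%), against 34.4% in length-matched lists. This share depended on the upstream extension, at 12.8% with 0 kb and 66.7% with 5 kb, the latter at the 99.4th percentile, and the median window was 2.69 kb and 7.69 kb under the same settings. With 2 kb, windows overlapped for 6 HOXA, 4 HOXB, 2 HOXC and 2 HOXD genes. HOXA3 had the longest window at 34.4 kb and the most start sites, 3, and its annotated body contained the whole window of HOXA4. HOXD12 had the shortest, at 2.96 kb. HOXA10 (ENSBTAG00000040082, chromosome 4, 68862439 to 68872086) shared 30.4% of its window with those of HOXA11 and an unnamed gene. HOXC10 (ENSBTAG00000003278, chromosome 5, 26042341 to 26047427) shared none.

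**Figure D2:**
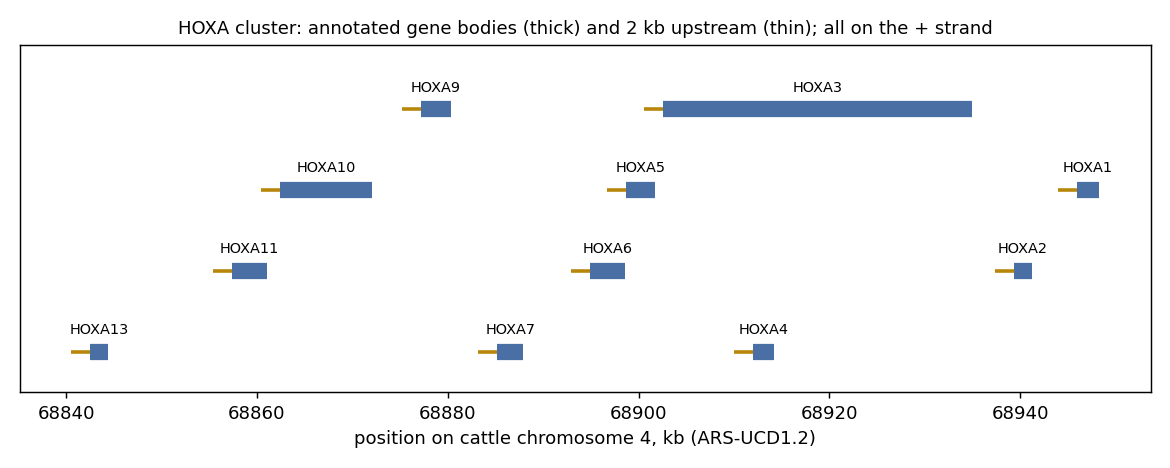
Map of the 11 HOXA genes on cattle chromosome 4 (horizontal axis, position in kb, ARS-UCD1.2), drawn to scale on staggered rows with thick bars for annotated gene bodies and thin bars for the 2 kb upstream that completes each gene-activity window. The window of HOXA4 falls inside the body of HOXA3.

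Antler bone and cartilage genes had a median window of 13.5 kb, within the central 95% of random lists at the 14.4th percentile. RUNX2, the osteoblast transcription factor gene, had the longest window of all lists at 353 kb (ENSBTAG00000004104, chromosome 23, 18594098 to 18945527) and shared 14.4% of it with that of SUPT3H. SOX9, the cartilage transcription factor gene, had a window of 5.60 kb (ENSBTAG00000045824, chromosome 19, 58919579 to 58923174). The window of COL10A1, the collagen gene of hypertrophic cartilage, lay wholly within that of NT5DC1. BGLAP, the osteocalcin gene, had the shortest window at 3.05 kb, and ALPL had 4 start sites.

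Median windows of endothelial, pericyte and pan-fibroblast markers each lay within the central 95% of random lists, and these lists were not tested against each other. Endothelial markers had a median of 56.8 kb (97.0th percentile), from LYVE1 at 16.3 kb to FLT1 at 207 kb, and 8 of the 11 had 2 start sites. PECAM1 had the most shared window among them, at 6.05%. Pericyte and smooth muscle markers had a median of 38.3 kb, from DES at 9.17 kb to ABCC9 at 152 kb, and MYH11 shared 14.9% of its window with that of NDE1. Pan-fibroblast markers had a median of 17.96 kb, from THY1 at 7.90 kb to FBLN1 at 82.6 kb. In that list APOD shared 19.3% of its window and MFAP5 and FBLN1 had 3 start sites. PDGFRA, the platelet-derived growth factor receptor gene used to mark fibroblasts, lay on chromosome 6 from 69723655 to 69771549 with a window of 49.9 kb.

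Myeloid markers had a median window of 17.1 kb, from S100A8 at 3.25 kb to the macrophage mannose receptor gene MRC1 at 115 kb. CD68 shared 43.9% of its window with those of EIF4A1 and MPDU1, and TREM1 and NOS2 had 2 start sites each. Lymphoid markers had a median of 9.19 kb (2.30th percentile, and 2.62nd without genes over 500 kb), from GNLY at 4.44 kb to IL7R at 36.7 kb. The T cell receptor complex genes CD3D, CD3E and CD3G each lay wholly within other windows, in every case including that of MPZL2. Of the 14 lymphoid markers, 6 (42.9%, 95% interval 17.7 to 71.1%) shared part of their window, against 37.0% in length-matched lists (68.0th percentile). With 5 kb upstream 71.4% did, against 50.8% (93.6th percentile). Both shares thus lay within the central 95% of random lists, and the genes counted include the neighbours CD3D, CD3E and CD3G. CD3G, CD4 and NKG7 had 2 start sites.

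Mast cell markers had a median of 11.3 kb, from TPSB2 at 5.33 kb to the receptor gene KIT at 89.4 kb. None of the 7 shared its window, for which the 95% interval reached 41.0%, and GATA2 and TPSB2 had 3 start sites. Keratinocyte markers had a median of 8.49 kb (2.97th percentile), from KRT10 at 6.36 kb to TP63 at 302 kb, and KRT17 shared 6.49% of its window with that of KRT42. Schwann and melanocyte markers had a median of 18.2 kb, and the longest was that of MITF at 228 kb. MITF, the melanocyte transcription factor gene, had 6 start sites, the most of any list gene, and PMEL shared 43.9% of its window with that of CDK2.

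**Figure D3:**
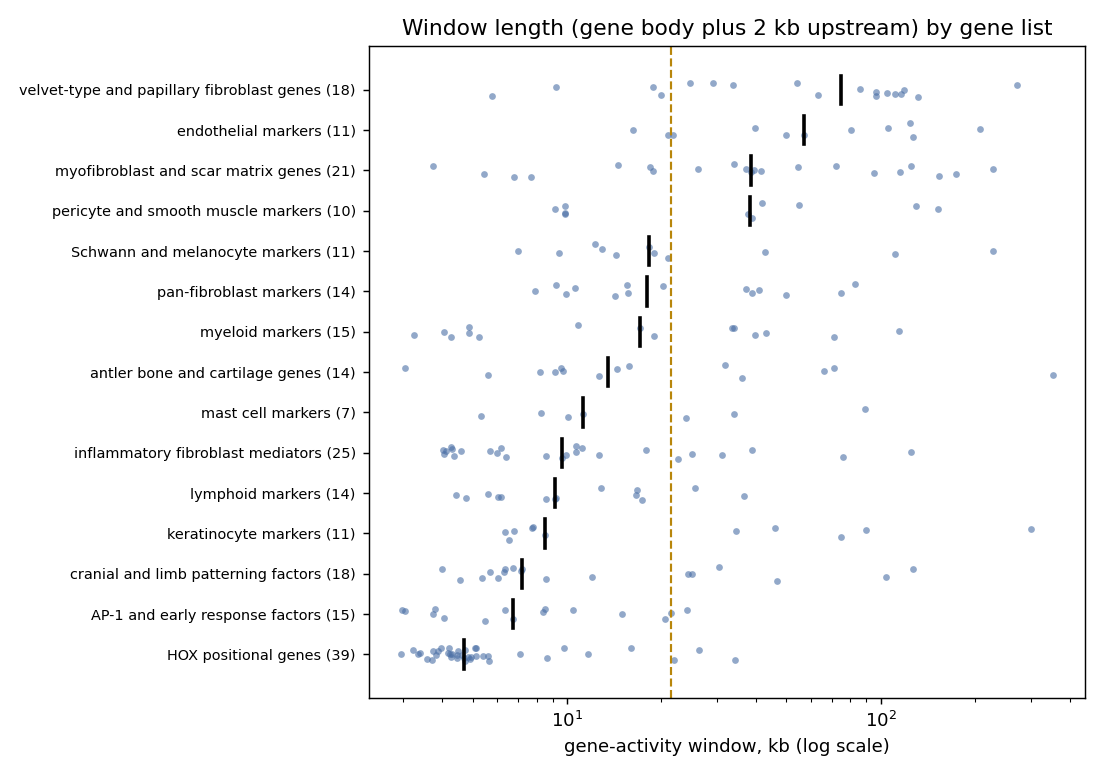
Length of the gene-activity window (horizontal axis, kb, log scale) for each coding gene of the 15 lists, 1 point per gene, with list sizes in parentheses, a black bar at each list median and a dashed line at the 21.4 kb median of named protein coding genes. The velvet-type list has the longest median, 74.6 kb, and the HOX list the shortest, 4.69 kb.

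Over the 15 lists and 3 measures, 14 of 45 percentiles fell outside the central 95%, where 2.25 would by chance if lists were random draws and each measure were continuous; shares and start-site counts in small lists are not. Median windows were short for inflammatory mediators, AP-1 factors, HOX genes, cranial and limb factors and lymphoid markers, and long for velvet-type genes. The lymphoid median lay at the edge of the central 95%, at the 2.30th percentile and at the 2.62nd without genes over 500 kb. Shared windows were few for inflammatory mediators, AP-1 factors, cranial and limb factors, pan-fibroblast markers and mast cell markers. For some of these lists the 95% interval still held the length-matched mean. These were AP-1 factors (0.169 to 31.9%, mean 31.0%), pan-fibroblast markers (0.181 to 33.9%, mean 31.5%) and mast cell markers (0 to 41.0%, mean 34.3%). No random list can lie below a share of 0, so the 2.385th percentile of mast cell markers came from ties alone. Start sites were few for inflammatory mediators, HOX genes and myeloid markers. AP-1 factors had the same number of genes (15) and the same mean (1.13) as myeloid markers, yet lay at the 2.605th percentile. Myeloid markers lay at the 2.475th, so only the random lists drawn set these 2 lists apart. The count of 14 thus depends in part on that draw. Of the 5 low shares, that of inflammatory mediators stayed outside the central 95% under all 4 overlap alternatives, and the other 4 did not. Of the 3 low means of start sites, that of HOX genes stayed outside once starts within 500 bases were merged, while inflammatory mediators moved to the 4.09th percentile and myeloid markers to the 11.8th. Taking all 243 genes at once, 44 windows (18.1%, 95% interval 13.5 to 23.5%) overlapped another coding window, against 32.4% in length-matched lists and below all 10000 of them. With 0 and 5 kb upstream the share was 8.64% and 28.4%. For 7 genes the whole window lay within others. A single start site was annotated for 178 of the 243 genes, and the mean was 1.35 per gene, at the 0.135th percentile.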

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

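The 3 kb distance for head-to-head neighbours, the inclusion of overlapping starts and the omission of HOX genes, reported with the other observations, were chosen only after the data were seen. With 0 or 5 kb upstream, the velvet-type median was 72.6 or 77.6 kb and the inflammatory median 7.62 or 12.6 kb. The extension changes every window by the same length, and neither list holds a gene over 500 kb. The medians under these settings, and without genes over 500 kb, were thus fixed in advance and are no check on the difference. Shares of overlapping windows depended on the upstream extension by construction. With 0 kb, the share fell to 8.64% over all lists, 12.8% for HOX genes and 0% for inflammatory mediators, cranial and limb factors and keratinocyte markers, and median windows fell to 2.69 kb (HOX), 5.16 kb (cranial and limb) and 6.49 kb (keratinocyte). With 5 kb, the share rose to 28.4% over all lists and 66.7% for HOX genes (99.4th percentile, against the 58.1st with 2 kb). For lymphoid markers it rose to 71.4% (93.6th percentile, against the 68.0th with 2 kb), and the HOX median window rose to 7.69 kb. Counting neighbours of any biotype gave 24.3% over all lists. A minimum overlap of 10% gave 12.8% over all lists, 4.76% for myofibroblast genes and 0% for endothelial and keratinocyte markers. The direction of these shifts in shares and windows follows from how each setting defines a window or an overlap. Why the HOX share with 5 kb rose above its length-matched lists (66.7% against 46.9%) was not tested. The low share of inflammatory mediators stayed at or below the 0.965th percentile under these 4 settings. With 0 kb, the low shares of AP-1 factors, pan-fibroblast markers, mast cell markers and cranial and limb factors rose to the 25.9th, 22.02nd, 15.3rd and 2.75th. Without genes over 500 kb, lymphoid median windows moved from the 2.30th to the 2.62nd percentile. With 0 and 5 kb upstream, which change every window alike, they lay at the 2.40th and 2.48th. Such movement thus arises in part from the random lists drawn. Leaving out long genes lowered the median of the genes drawn from, from 21.4 to 21.0 kb, and changed no list median. Apart from the draw, this by itself raises percentiles. How much of the move to the 2.62nd percentile came from it was not tested. Merging starts within 500 bases lowered the mean number of starts to 1.25 over all lists. Matching without regard to case found 244 genes and restriction to coding genes 243. Fragments per cell were not analysed here, so what depth limits was not tested. No paired analysis was possible because the groups share at most 1 animal number in the labels.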

Other observations

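Of the tests below, all 3 on the window lengths of velvet-type and inflammatory genes, the head-to-head and 5' UTR measures (30 further list percentiles) and their alternatives were chosen only after the data were seen. None of these observations concerns accessibility.

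None of the 243 coding list genes had a protein coding neighbour transcribed in the opposite direction from a start within 1 kb upstream (Clopper-Pearson 95% interval 0 to 1.51%), whereas 6.47% of named protein coding genes did, which would give 15.7 genes. Starts this close always give overlapping windows with 2 kb upstream. The count is therefore part of the low share of overlapping windows over all lists, not a separate result. The interval and the expected number treat genes as independent draws. However, the 39 HOX genes lie in clusters, each on a single strand, where they cannot be head-to-head neighbours of each other. Counting overlapping starts as well gave 2 genes, ACTA2 and PECAM1 (0.823% against 8.76%), and widening the distance to 3 kb gave CD3D, CD3G, DLX6 and FOXP3 (1.65% against 9.16%). These genes were named here after their values were seen. Annotated 5' UTRs were present for 84.8% of list genes and 77.0% of named coding genes. Single lists were too small to fall below the 2.5th percentile for head-to-head neighbours even at a count of 0, so that measure rests on all lists together. For 5' UTRs, 3 of the 15 list percentiles fell outside the central 95%. HOX genes were low, with a 5' UTR for 22 of 39 (56.4%, 0.26th percentile), and inflammatory mediators (96.0%, 99.2nd) and lymphoid markers (100%, 98.7th) were high. Without HOX genes the share over all lists was 90.2%. Unnamed coding genes had a 5' UTR in 23.1% of cases.

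The absence of head-to-head neighbours was weighed against a definition effect and against gene-poor surroundings. With overlapping starts counted, the list share was still below all 10000 random lists (percentile 0), which argues against the definition. Against random lists matched on the number of coding genes starting within 500 kb, the share was again below all 10000 (percentile 0). This argues against gene-poor surroundings at that scale only. The matching moved the expected number little, from 15.7 genes to 15.0. It cannot decide whether list genes stand apart from neighbours at the scale of 1 kb, since spacing at that scale was not matched. A hypothesis that remains is that genes chosen as markers and regulators are cell-type restricted, while bidirectional promoters may be commoner among broadly expressed genes; it was not tested, since the lists were chosen by hand and no expression values were used.

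The difference in window length between velvet-type and inflammatory lists was weighed in the same way. Without its 5 longest genes, the velvet-type list had a median of 33.7 kb, against 21.4 kb for named coding genes. A median moves little with a few extreme genes, and this criterion was set after the lengths were seen. It therefore cannot decide what part a few very long genes play. A 5' UTR was annotated for 96.0% of the inflammatory mediators, above the 77.0% of named coding genes, and for 88.9% of the velvet-type genes. This argues only against inflammatory gene models that lack a 5' UTR altogether. Any 5' UTR record counted, so models that have one but miss further 5' sequence cannot be told apart. This criterion, too, was set after the data were seen. A chance difference between 2 lists of genes stays open: the permutation p was 0.00038 for this pair alone and 0.102 with its choice from 15 lists allowed for. If gene scores are sums of fragments over these windows, a hypothesis is that equal promoter opening may weigh less in the score of a 74.6 kb window than in one of 9.62 kb; it was not tested, since it needs the fragments.

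The annotation carried 2 name fields on 20441 genes, the first a symbol and the last a repeat of the Ensembl identifier; the other 7166 genes had the identifier alone. Read with rtracklayer, all 27607 genes came out named by identifier and 0 by symbol. With the last field removed from those records, 20441 genes came out with a symbol, which is what the appended second name field as the cause predicts. Whether the study's own gene scores were labelled by identifier or by symbol was not tested.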
